A study of Rattus norvegicus with 24 samples.

How the data were processed

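RNA from the left ventricle of rat hearts was measured on 24 arrays, 1 array per sample. Per the labels, each sample was total RNA of an operated rat, taken 1 or 7 days after an operation that either produced a myocardial infarction (MI) or was a sham operation. Each of the 4 groups held 6 arrays. Groups were taken from the titles. The labels do not say outright that each array held a different animal, so p-values measure the spread between these samples, which may in part be technical. The free-text descriptions of the day 1 sham samples name 7 days, while their titles and keywords name 1 day, and the titles were used. Per the labels, MI samples left out the infarct zone and sham samples were the whole left ventricle with septum, so the part of the heart sampled differed between the operations.

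The values used were the intensities deposited by the authors in a single table of 1185 probes, 702 with IDs starting in R and 483 in RG. They were positive linear intensities, deposited with a median over the listed probes of 91.1 to 107.5 per array. Probe R371 was exactly 100 on all 24 arrays, and was left out of every test. How spots were scanned, how background was treated, what the scaling was set to and why cells were left blank are not given in the sources used here. Of all cells, 63.3% were blank, and blank cells were treated as missing and never filled in. Because the rule for blanks is unknown, a blank was read neither as a low level nor as absence. The IDs were not paired with gene names: 0 of them matched the gene name table at hand. Probes are therefore given by ID, and the 22 gene lists fixed before the data were examined could not be tested. Columns of samples from another series numbered 0, and 0 pairs of arrays held identical values.

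Intensities were put on the log2 scale as deposited, with no added constant and no further scaling. A model with 1 mean per group was fitted to all 24 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method. A probe was called changed at an adjusted p under 0.05. The contrasts were MI against sham at day 1 and at day 7, the difference between these 2 effects (the interaction), and day 7 against day 1 within each operation. A probe entered a contrast when it had at least 3 listed values in each group compared. This minimum was chosen after seeing the data, and 2 and 6 values were tried beside it. Adjusted p-values below are from this limma model unless another test is named. Fold changes are ratios of geometric means over the listed values. Group levels are arithmetic means ± SD of the deposited intensities, with n the number of arrays that listed the probe. The rule for naming probes, fixed before the data were examined, took for unnamed IDs up to 2 probes up and 2 down per contrast, by fold among called probes with a mean log2 intensity at or above the lower quartile, or by p where no probe passed. Any other probe is named as chosen after its values were seen.

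Counts of listed probes were compared by two-sided exact permutation tests, and overlaps by Fisher's exact test, with scipy 1.17.1 under Python 3.11.15. The model was tested on simulated tables with the blanks of the real ones and each probe's level and spread, in which 20 probes per fold size were changed. Noise was drawn independently for each probe and array, so differences in level between whole arrays were not simulated. All fold sizes were changed within each table. With fewer changed probes the Benjamini-Hochberg method asks for smaller p-values, so the shares recovered could be lower. The rates that follow hold for such tables and may not hold for the real arrays. With deposited scaling, it recovered 24.0% of probes changed 1.5-fold, 66.2% of those changed 2-fold and 95.0% of those changed 3-fold at day 1 (283 probes). The shares at day 7 (486 probes) were 27.2%, 70.5% and 97.2%. Of the calls, 3.52% at day 1 and 4.18% at day 7 were false. With complete-probe scaling it recovered 58.5%, 89.5% and 98.2% at day 1 and 50.0%, 88.0% and 98.8% at day 7, and 3.62% of calls at day 1 and 6.24% at day 7 were false. The number of arrays limits the precision.

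Alternatives listed before the data were examined were quantile normalization, median centring, adding 16 before the log, leaving out the dimmest 25% of probes, fitting only the groups compared, an intensity trend with robust eBayes, leaving out each array, the runs of title numbers as a block, leaving out arrays A535 to A538, pooling both sham groups, and stricter thresholds. The array titles carry numbers from A501 to A538, which form 5 runs. Each run held both operations and 1 day only. Arrays A507 to A512, all from day 1 with 3 of each operation, listed fewer than 300 probes each and are called sparse arrays. Alternatives added after seeing the data were leaving these out, using sparse or not as a block, and a different scaling called complete-probe scaling. In the latter, each array was shifted on the log2 scale so that the mean over the 94 probes listed on every array (without R371) was equal.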

Results

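The arrays compared rat left ventricle after myocardial infarction (MI) with left ventricle after a sham operation, 1 day and 7 days after surgery, with 6 arrays in each group. Of 1185 probes, 923 had a value on at least 1 array and 95 on every array. Probes listed on every array were brighter, with a median mean intensity of 271.8, than probes listed on 1 array, with 53.2. Within groups, the correlation of log2 intensities between arrays, across probes (which are not independent replicates), ranged from 0.750 to 0.935 in day 1 sham, 0.840 to 0.966 in day 1 MI, 0.837 to 0.975 in day 7 sham and 0.811 to 0.962 in day 7 MI.

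The number of listed probes varied widely between arrays. It was 552 ± 42.9 (SD, n = 6) in day 7 MI and 503.2 ± 99.6 (SD, n = 6) in day 7 sham (two-sided exact permutation p = 0.290, adjusted p = 0.435 over 6 comparisons). At day 1 it was 364.3 ± 132 (SD, n = 6) in MI and 321 ± 172 (SD, n = 6) in sham (exact permutation p = 0.610, adjusted p = 0.732). Day 7 arrays listed more probes than day 1 arrays by 188 on average in MI (exact permutation p = 0.00649, adjusted p = 0.0390) and by 182 in sham, where the difference did not pass (exact permutation p = 0.0671, adjusted p = 0.200). The 6 sparse arrays of day 1 listed 141 to 296 probes, and the other 18 arrays listed 404 to 684. Among the sparse arrays, MI listed 249 ± 48.0 and sham 171 ± 28.1 probes (SD, n = 3 each), with an exact permutation p = 0.100, the smallest that 3 against 3 allows. On the deposited scale, the median intensity of the complete probes was 117.5 to 250.3 on the sparse arrays and 241.7 to 338.3 on the others, so day 1 values carried a difference in level between arrays. Across the 6 sparse arrays, the mean log2 intensity of the complete probes rose with the number of listed probes (Pearson r = 0.949, exact permutation p = 0.0139, adjusted p = 0.0278; Spearman rho = 0.829, exact permutation p = 0.0583, adjusted p = 0.117). Without the 2 arrays farthest from the median, r was 0.893. MI and sham arrays were pooled in these correlations. Each array's listed values had a median of 91.1 to 107.5, so a list limited to brighter probes places the complete probes nearer that median. The relation across the sparse arrays may therefore follow from the scaling or the operation. Across the other 18 arrays r was 0.178 (permutation p = 0.482) and rho 0.170 (permutation p = 0.496).

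**Figure D1:**
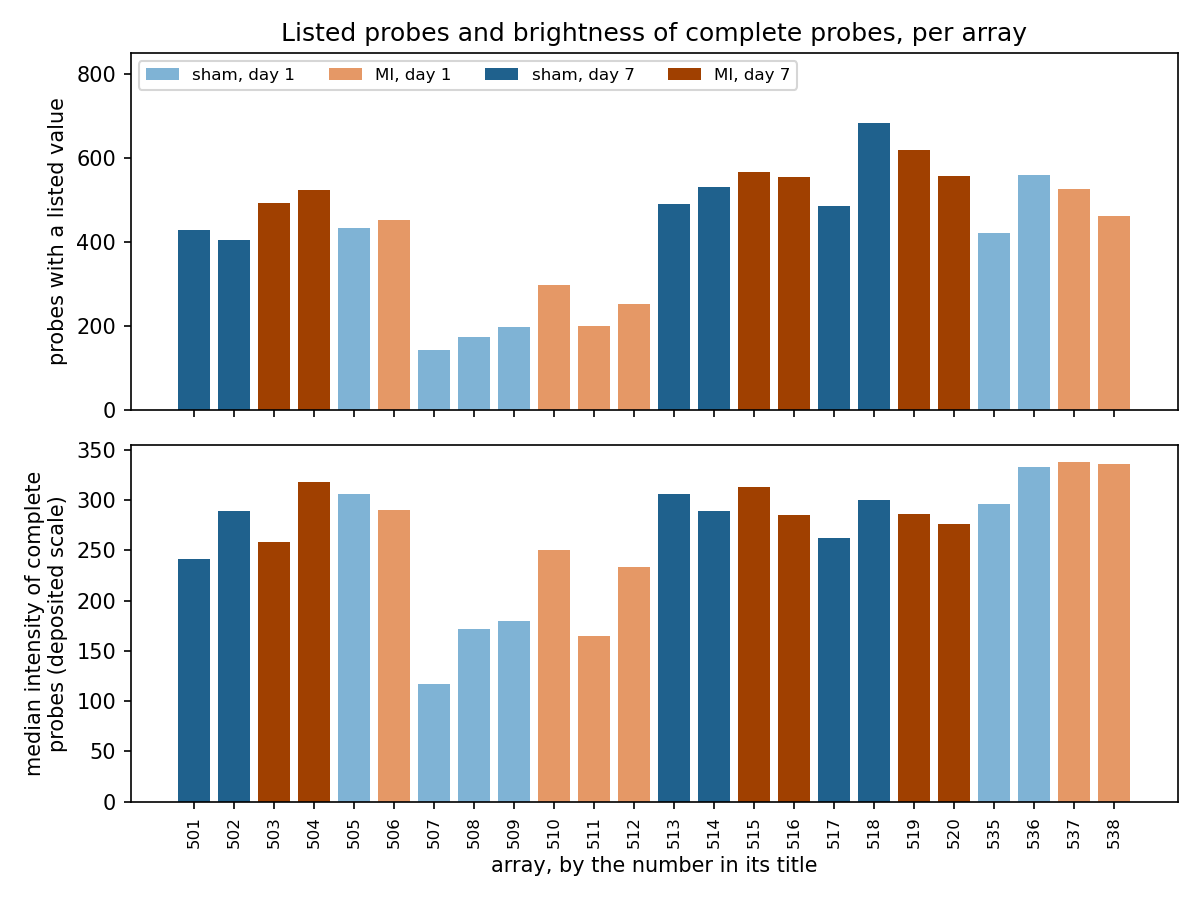
Bars give, for each of the 24 arrays in order of title number, the number of probes with a listed value (top) and the median deposited intensity of the probes listed on every array (bottom, linear scale), coloured by group. Arrays A507 to A512 list 141 to 296 probes and have complete-probe medians of 117.5 to 250.3.

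At 7 days, 7 of 486 probes were higher in MI than in sham left ventricle and 0 were lower. Probe R272 rose 2.98-fold, from 44.0 ± 15.8 (SD, n = 5) in sham to 127.7 ± 27.5 (SD, n = 5) in MI (log2 fold change 1.58, SE 0.25, adjusted p = 0.000599). Probe RG433 rose 2.51-fold, from 103.8 ± 34.2 (SD, n = 6) to 254.7 ± 48.1 (SD, n = 6), with a log2 fold change of 1.33 (SE 0.20, adjusted p = 0.000352). For both probes every listed MI value lay above every listed sham value, with R272 at 93.6 to 163.8 against 29.5 to 69.5 and RG433 at 195.4 to 318.3 against 77.0 to 171.3. The 7 probes rose 1.71-fold to 2.98-fold.

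The day 7 rises of R272 and RG433 were seen in each of the 3 runs of title numbers at day 7. For R272 the log2 difference was 1.30 in arrays A501 to A504 (1 array of each operation), 2.09 in arrays A513 to A516 and 1.21 in arrays A517 to A520 (2 of each). For RG433 it was 1.27, 1.41 and 1.31 in the same order, with 2 arrays of each operation per run. With the runs as a block, 17 probes were called, all higher in MI and including all 7, and the adjusted p was 0.00109 for R272 and 6.64e-05 for RG433. With complete-probe scaling 12 probes were called, again all higher and including all 7, with a range of 1.62-fold to 2.87-fold. Leaving out a single array gave 2 to 8 called probes, and quantile normalization gave 4.

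At 1 day, 0 of 283 probes passed the limma test with the deposited scaling, and 22 had an unadjusted p under 0.05. The smallest adjusted p was 0.0502, shared by probes RG316 and R364. RG316 was at 384 ± 77.7 in MI and 198 ± 66.6 in sham (SD, n = 6 each), a log2 difference of 1.02 (SE 0.25). R364 was at 387 ± 47.7 in MI and 231 ± 79.3 in sham (SD, n = 6 each), a log2 difference of 0.82 (SE 0.20). Named by the same rule in the other direction, R706 was at 83.3 ± 36.3 in MI and 136.4 ± 5.37 in sham (SD, n = 3 each; log2 difference -0.79, SE 0.32, adjusted p = 0.380). RG236 was at 67.6 ± 23.3 in MI and 106.6 ± 27.7 in sham (SD, n = 3 each; log2 difference -0.69, SE 0.33, adjusted p = 0.646).

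The day 1 result changed with the scaling. Complete-probe scaling, chosen after seeing the data, moved the median log2 difference over all 283 probes from 0.12 to -0.02 and gave 10 called probes, all higher in MI, by 1.44-fold to 2.35-fold. Relative to that shift, RG316 was higher by 0.75 (SE 0.18, adjusted p = 0.0145) and R364 by 0.54 (SE 0.10, adjusted p = 0.00317) on the log2 scale. The deposited log2 difference of RG316 was 1.13 in arrays A505 to A512 (4 of each operation) and 0.82 in arrays A535 to A538 (2 of each), and that of R364 was 0.99 and 0.46. With these runs as a block, 6 probes were called on the deposited scale, and both RG316 and R364 had an adjusted p of 0.0125. Without the sparse arrays, which left 3 arrays per group, 0 probes were called on the deposited scale (18 of 251 at an unadjusted p under 0.05) and 1 with complete-probe scaling. RG316 then had a deposited log2 difference of 0.74 (SE 0.25, adjusted p = 0.269) and R364 of 0.48 (SE 0.15, adjusted p = 0.224).

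**Figure D2:**
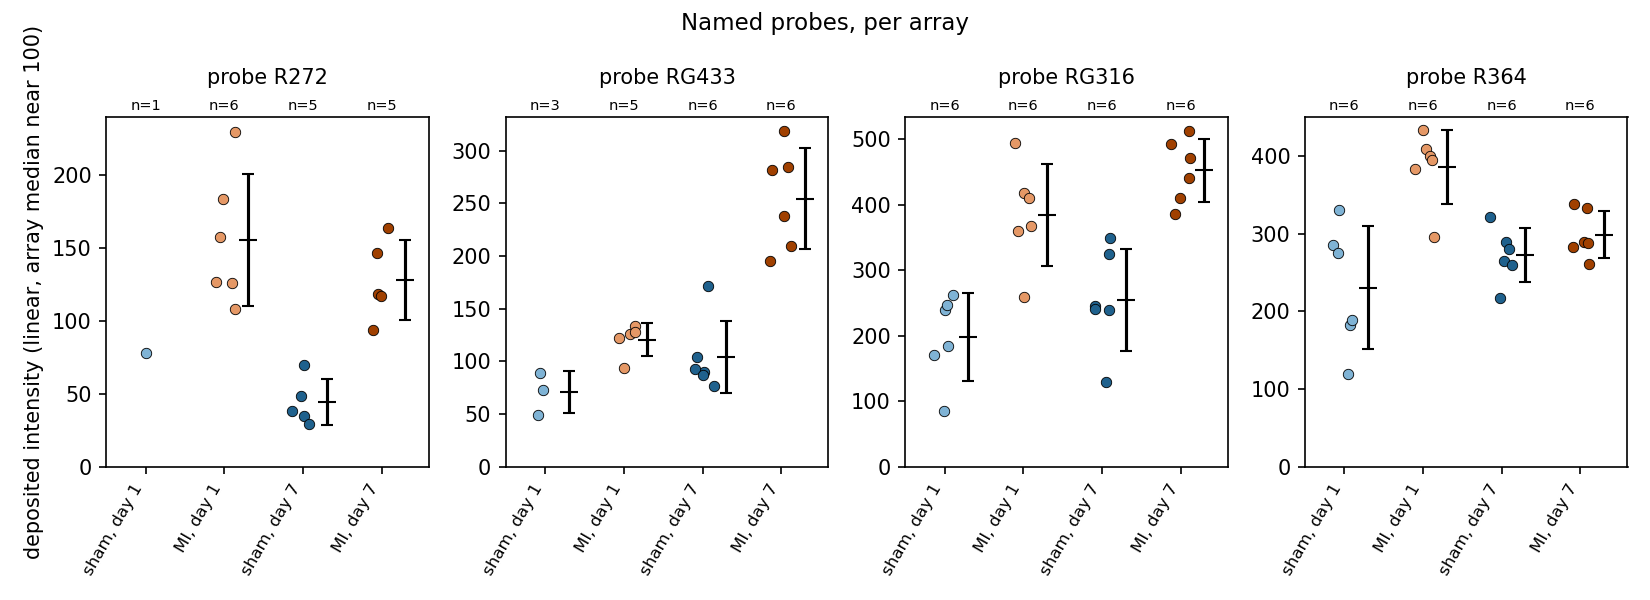
Each point is the deposited intensity (linear axis from 0) of 1 array for probes R272, RG433, RG316 and R364, grouped by operation and day, with n listed arrays above; horizontal ticks and bars are mean ± SD where n exceeds 1. R272 at day 7 lies at 93.6 to 163.8 in MI and 29.5 to 69.5 in sham, and RG433 at 195.4 to 318.3 and 77.0 to 171.3.

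The difference between the day 7 and day 1 effects of MI was tested directly, and 0 of 275 probes passed in limma with the deposited scaling (7 at an unadjusted p under 0.05, smallest adjusted p = 0.936). With complete-probe scaling 0 passed as well (12 at an unadjusted p under 0.05, smallest adjusted p = 0.723). Of the probes called at day 7, only 2 of 7 as deposited and 3 of 12 with complete-probe scaling were among the 275. The others were not tested for a difference between the days. R272 was one of these, since only 1 day 1 sham array listed it, at 77.8. In day 1 MI it was at 155.1 ± 45.2 (SD, n = 6). The probes named by the rule, R542 and RG534 upward and R681 and R364 downward, had interaction log2 values of 1.12 (SE 0.45), 0.92 (SE 0.38), -0.81 (SE 0.32) and -0.68 (SE 0.29), each with adjusted p = 0.936. With complete-probe scaling these were 1.10 (SE 0.45), 0.45 (SE 0.30), -0.44 (SE 0.25) and -0.44 (SE 0.15), with adjusted p of 0.839, 0.967, 0.967 and 0.723. For R364, the MI effect was 0.82 at day 1 and 0.14 (SE 0.19, adjusted p = 0.967) at day 7, a difference that did not pass.

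Both days were compared over the 275 probes tested at each. With the deposited scaling, 0 probes were called at day 1, so 0 were shared, and the log2 fold changes of the 2 days had r = 0.213 and rho = 0.174 across probes, which are not independent replicates. With complete-probe scaling, 3 of these probes were called at day 7 and 10 at day 1, and 3 were shared, against 0.109 expected for independent lists (two-sided Fisher's exact p = 3.50e-05). That test treats probes as independent, and both contrasts used the same estimate of each probe's spread, so its p may be too small. The correlations were then r = 0.441 and rho = 0.400 across probes. All 10 probes called at day 1 also had a positive log2 fold change at day 7, whether or not they passed there; over all 275 probes, 182 had the same sign on both days. The shared probes, chosen after their values were seen, were RG316, RG433 and R642. On that scale RG316 was higher in MI by 0.75 (SE 0.18) at day 1 and 0.85 (SE 0.18) at day 7, RG433 by 0.94 (SE 0.24) and 1.29 (SE 0.19), and R642 by 1.23 (SE 0.24) and 1.04 (SE 0.22). At day 1, RG433 had 5 MI and 3 sham values and R642 had 6 and 3, with no sham value from a sparse array. As deposited, their day 1 differences were 0.81 (limma adjusted p = 0.203) and 0.98 (adjusted p = 0.118). Without the sparse arrays and with complete-probe scaling they were 0.88 and 1.12.

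**Figure D3:**
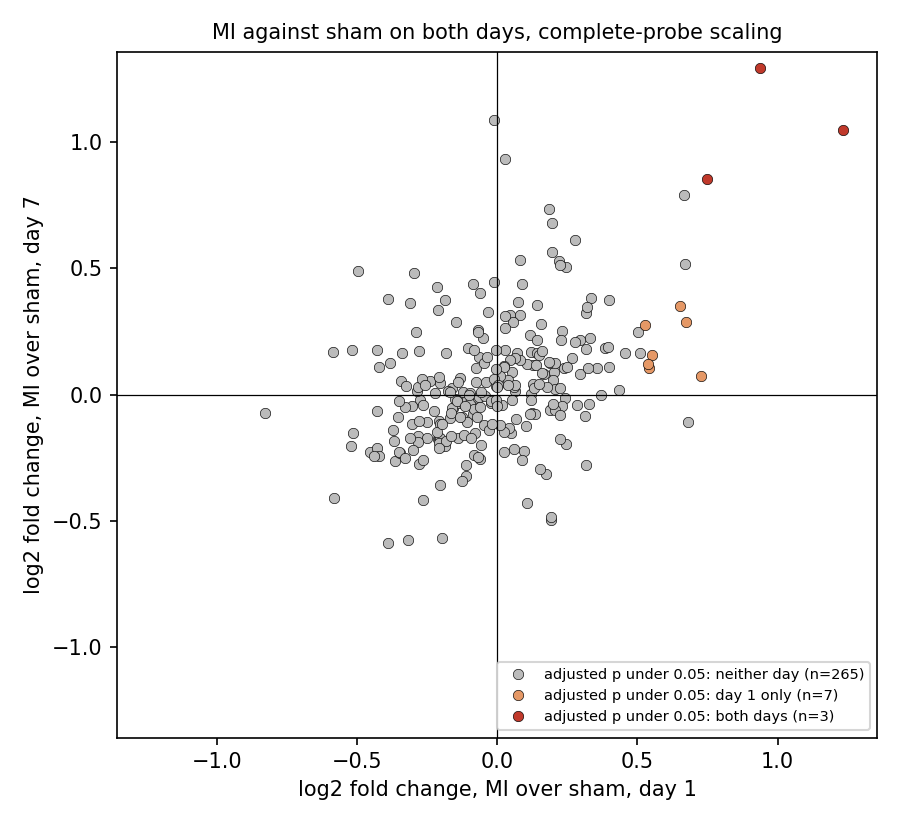
Each point is 1 of 275 probes tested on both days, with the log2 fold change of MI over sham at day 1 on the horizontal axis and at day 7 on the vertical axis, after complete-probe scaling; colours mark an adjusted p under 0.05. The 3 probes called on both days lie in the upper right, and the 7 called at day 1 alone are also above 0 at day 7.

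In MI left ventricle, 9 of 354 probes were higher at day 7 than at day 1 and 1 was lower. Probe R418 rose 2.65-fold, from 57.4 ± 10.2 (SD, n = 4) to 152.4 ± 28.1 (SD, n = 6), with a log2 fold change of 1.40 (SE 0.24, adjusted p = 0.00322). Probe R345 rose 2.29-fold, from 99.5 ± 50.1 (SD, n = 5) to 205.7 ± 24.4 (SD, n = 6), with a log2 fold change of 1.20 (SE 0.33, adjusted p = 0.0399). R345 was also higher at day 7 in sham, by 0.98 on the log2 scale (SE 0.35, adjusted p = 0.138) as deposited. With complete-probe scaling its sham difference passed, at 0.92 (SE 0.26, adjusted p = 0.0372). Its deposited interaction value was 0.22 (SE 0.48, adjusted p = 0.936), so the rise was not shown to differ between the operations. Probe R630 fell by 0.86 on the log2 scale (SE 0.22, adjusted p = 0.0304), from 486 ± 113 to 265 ± 48.5 (SD, n = 6 each). RG433, named for its day 7 rise over sham, was also higher at day 7 than at day 1 in MI (log2 fold change 1.07, SE 0.22, adjusted p = 0.00573). Its sham difference between the days had the same direction but did not pass, at 0.55 (SE 0.26, adjusted p = 0.218) as deposited. With complete-probe scaling that sham difference was 0.72 (SE 0.23, adjusted p = 0.0588). The deposited interaction value of RG433 was 0.52 (SE 0.34, adjusted p = 0.936). Days did not share a run of title numbers, so no value within a run can be given; with the runs as a random block 1 probe was called, R418 (adjusted p = 0.0342), and R345 and R630 each had an adjusted p of 0.339. Without the sparse arrays, 8 probes were called, 4 higher and 4 lower, of which 4 were among the original 10, 7 of which could still be tested; R630 stayed lower (log2 difference -1.12, adjusted p = 0.00325) and R345 did not pass (0.74, adjusted p = 0.183). Complete-probe scaling gave 64 called probes, 56 higher and 8 lower, including all 10.

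In sham left ventricle, 1 of 322 probes was called between the days, and 69 had an unadjusted p under 0.05. Probe R058 was higher at day 7, at 264 ± 39.6 (SD, n = 6), than at day 1, at 112 ± 87.2 (SD, n = 4), with a log2 fold change of 1.49 (SE 0.32, adjusted p = 0.0321), and of 0.87 (SE 0.18, adjusted p = 0.00976) with complete-probe scaling. Of the 4 day 1 values, 3 lay at 53.2 to 84.2 and came from sparse arrays, and the remaining value was 241.6. With the runs of title numbers as a random block R058 had an adjusted p of 0.629, and without the sparse arrays it had too few values to be tested. R630 was lower at day 7 by 0.69 (SE 0.22) on the log2 scale in sham, which did not pass (adjusted p = 0.130); with complete-probe scaling its sham difference was -1.04 (SE 0.18, adjusted p = 0.00123). Complete-probe scaling gave 24 called probes in sham, 21 higher and 3 lower, and 0 of 305 probes passed without the sparse arrays (48 at an unadjusted p under 0.05).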

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

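The tests of sparse arrays, scaling and runs of title numbers in this part, and the reading of the counts over other splits of the arrays, were fixed only after the results they concern had been seen. Each set of splits held 100 groupings of the same arrays into groups of the same sizes, the real one included.

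In 7 of 48 groups of 4 to 6 values, a single array stood apart from the others. Chance alone gives about 1 in 20, but that rate is only a rough guide here. The probes were named for their results, and deposited intensities of sparse and other arrays were mixed. In day 1 MI, R364 was 295.6 on replicate 3, a sparse array, against 384.4 to 434.6 on the others. In the same group RG433 was 93.3 on replicate 4, also a sparse array, against 122.3 to 133.5, and R542 was 118.4 on replicate 1 against 46.6 to 62.1. RG534 was 116.2 on replicate 1, its only value from outside the sparse arrays, against 47.3 to 53.4. In day 1 sham, R542 was 105.7 on replicate 6 against 50.6 to 57.0. R058 was 241.6 on replicate 1, its only value there from outside the sparse arrays, against 53.2 to 84.2. In day 7 sham, RG433 was 171.3 on replicate 1 against 77.0 to 104.4, still under the lowest MI value of that day.

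The day 7 rise of 7 probes in MI, with none falling, was weighed first. The real grouping called 7 probes and the highest of the other splits 3, so 1 of 100 splits gave as many and chance can be excluded at that level; with complete-probe scaling the counts were 12 and 1, and again 1 of 100 splits gave as many. A shift of whole arrays by the authors' scaling is argued against, since 7 of the 7 probes were still called after complete-probe scaling. That scaling changed little at day 7, moving the median log2 difference over the 486 probes from 0.052 to 0.028. Quantile normalization, which equalizes the whole distribution of each array, kept 4 of the 7 called, so other effects of scaling are not excluded. With the runs of title numbers as a block 7 of the 7 were still called, but this says little about a difference between runs. Each day 7 run held as many MI as sham arrays, so a shift of a whole run falls on both operations alike where no cells are blank. The log2 fold changes of R272 and RG433 were the same with the block as without it, at 1.58 and 1.33. Also left open is that MI samples lacked the infarct zone and sham samples did not. That difference in tissue follows the operation exactly and was not tested, and neither was a response of the surviving muscle to infarction.

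The upward shift of probes from day 1 to day 7 was weighed next, over the probes tested under every scaling and array choice (305 in sham, 311 in MI). Whether the 6 sparse arrays may account for it is undecided, because the scalings differ: without them the median log2 difference went from 0.28 to -0.022 in sham and from 0.21 to -0.060 in MI as deposited, but with complete-probe scaling from 0.21 to 0.14 in sham and from 0.19 to 0.12 in MI. Whether scaling each array to the probes it lists accounts for the shift is also undecided. Complete-probe scaling left 0.19 in MI (0.16 to 0.24 with each array left out). In sham it left 0.21 (0.10 to 0.24, with 0.11, 0.11 and 0.10 without day 1 replicates 1, 5 and 6). Without the sparse arrays, however, the same change of scaling raised the median, from -0.060 to 0.12 in MI and from -0.022 to 0.14 in sham. The shift left may therefore not be the deposited one, so these values cannot decide the question. Single arrays moved the deposited median as well, over a range of 0.21 to 0.51 in sham (0.46, 0.45 and 0.51 without day 1 replicates 1, 5 and 6) and 0.11 to 0.35 in MI (0.13, 0.11, 0.35 and 0.34 without day 1 replicates 2, 3, 5 and 6). As deposited, 7 of 100 splits of the sham arrays called at least the real 1 probe (highest other 94), so chance cannot be excluded there, and 1 of 100 splits of the MI arrays called at least the real 10 (highest other 8), while with complete-probe scaling it was 1 of 100 in sham (24 real, 23 in the highest other) and 1 of 100 in MI (64 and 14). The count of 94 came from a split with all 3 sparse sham arrays in one group, as in the real grouping, and the 77 splits with 2 and 1 called at most 2, so the high counts follow the sparse arrays; a change with time after surgery stays open.

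The day 1 rises, absent as deposited and called under complete-probe scaling, blocking and some other settings, were weighed last. As deposited, the real count was 0, so 100 of 100 splits necessarily gave at least as many, which says nothing about chance. With complete-probe scaling 5 of 100 splits gave at least the real 10 (highest other 49), but the high counts went with an uneven division of the sparse arrays. As deposited, the 7 splits with 5 of them in one group called a median of 107 probes and up to 152, and the 42 other splits with 3 in each group, as in the real grouping, at most 2. With complete-probe scaling, where the pattern was weaker, the 6 splits with 5 in one group called a median of 5.5 and up to 49. The 52 splits with 4 in one group called a median of 0 and up to 11. Whether chance can be excluded thus depends on the splits. Over all splits it cannot, while the 41 other splits with 3 in each group called at most 4 against the real 10. With sparse or not as a block and complete-probe scaling, 2 of 100 such splits gave at least the real 11 (highest other 11). At that level this excludes chance for a count of changes in either direction. The real 11 included probes lower in MI, and rises alone were not counted over these splits, so chance was not tested for the rises by themselves. As deposited, 3 of 100 gave at least the real 19 (highest other 47). That count cannot part rises of single probes from a level difference within the sparse arrays, which the block leaves in. There the deposited complete-probe median was 216.0 ± 45.5 in MI and 156.3 ± 33.8 in sham (SD, n = 3 each, exact permutation p = 0.300).

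With complete-probe scaling and both sets of day 1 arrays fitted separately, the sparse arrays called 9 of 106 probes and the others 0 of 251, or 1 when the day 7 arrays shared the estimate of the spread. An effect in the sparse arrays alone is argued against for RG316, singled out after these values were seen: its log2 difference was 0.79 in the sparse arrays and 0.71 (SE 0.13) in the others, with an adjusted p of 0.0128 over the 9 probes. For the day 1 rises as a set it stays undecided. Of the 9 probes, 7 were higher in MI in the sparse arrays and kept that direction in the others. RG050 and RG361 were lower in the sparse arrays (-0.85 and -0.54) and stood at 0.0055 and 0.12 in the others. Over all 9, whatever their sparse direction, the median log2 difference in the others was 0.27. The exact permutation p for their mean was 0.100, the smallest that 3 against 3 allows. The 10 probes called with all arrays were each higher in MI in the others (median 0.44, 0.18 to 1.12), but these arrays helped to choose them. R364 was at 0.44 in the others (adjusted p = 0.0855) against 0.64 in the sparse arrays, and RG433, with no sparse sham value, at 0.88. Of the 20 probes with the lowest p in the other arrays, 18 had the same direction in the sparse arrays, against 66.7% of all 99 shared probes (one-sided exact binomial p = 0.0176, which treats probes as independent), and in the opposite direction 14 of 20 did (p = 0.479). The tissue difference between MI and sham samples stays open here too.

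For the interaction, 0 probes were called as deposited and with complete-probe scaling, so 100 of 100 splits necessarily gave at least as many in each case and chance was not tested; the highest other counts were 5 and 10.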

How the results depend on the processing

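Complete-probe scaling, the minimum of listed values per group, and every setting that treats the sparse arrays apart were chosen after seeing the data. Where a count moved, the cause was not tested, except that a minimum of 6 values, a stricter threshold or fewer arrays leaves fewer probes or less data. None of the named probes that passed turned direction in these settings. The interaction count was 0 in every setting run, each array left out included. R272 was called at day 7 in all 26 alternatives that tested it, RG433 in all 27, and R418 between the days in MI in all 22; R630 was called in 17 of 25, R345 in 14 of 24 and R058 in 12 of 22. RG316 at day 1 was called in 15 of 29 (adjusted p 0.00151 to 0.654) and R364 in 15 of 29 (0.000315 to 0.654). The interaction value of RG534, which never passed, reversed to -0.079 with sparse or not as a block and complete-probe scaling.

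For MI against sham at day 1, the count moved from 0 to 3 with quantile normalization, 2 after adding 16, 2 without the dimmest probes, 2 with trend and robust eBayes, 6 with title-number runs as a block, 3 without arrays A535 to A538, 2 against both sham groups, 10 with complete-probe scaling, 5 with 6 values per group, 1 without sparse arrays plus complete-probe scaling, 19 with sparse or not as a block, 11 (9 higher, 2 lower) with that block plus complete-probe scaling, and 13 (12 higher, 1 lower) with the runs plus complete-probe scaling. Leaving out single arrays gave 0 to 11, with 11 without sham replicate 1, 8 without sham replicate 6, 6 without MI replicate 3 and 2 without sham replicate 5.

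At day 7 the count moved from 7 to 4 with quantile normalization, 14 with only the groups compared, 17 with the runs as a block, 13 against both sham groups, 2 at an adjusted p under 0.01, 12 with complete-probe scaling, 2 with 6 values per group, 13 without sparse arrays, 13 (12 higher, 1 lower) with complete-probe scaling added, 15 with sparse or not as a block, and 14 (13 higher, 1 lower) with complete-probe scaling added. Leaving out single arrays gave 2 to 8, with 2 without MI replicate 5, sham replicate 4 or sham replicate 5, and 3 without MI replicate 3 or 4.

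Between the days in sham the count moved from 1 to 0 with only the groups compared, 0 with the runs as a random block, 80 without arrays A535 to A538 (which leaves mostly sparse arrays at day 1), 24 with complete-probe scaling, 3 with 2 values per group, 0 with 6 values, 0 without sparse arrays and 0 with complete-probe scaling added. Leaving out single arrays gave 0 to 45, with 45, 40 and 18 without day 1 replicates 6, 1 and 5, and 0 without day 1 replicates 2, 3 or 4 or day 7 replicates 2 to 6. In MI it moved from 10 to 19 with quantile normalization, 16 with only the groups compared, 16 with trend and robust eBayes, 1 with the runs as a random block, 41 without arrays A535 to A538, 64 with complete-probe scaling, 0 with 6 values per group, and 26 (23 higher, 3 lower) without sparse arrays plus complete-probe scaling; without sparse arrays alone it was 8 (4 higher, 4 lower). Leaving out single arrays gave 2 to 21, with 21, 19, 5, 4 and 2 without day 1 replicates 1, 5, 2, 4 and 6, and 4, 5, 4 and 4 without day 7 replicates 3, 4, 5 and 6. The overlap of both days moved from 0 to 3 with complete-probe scaling.

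Not run were a higher floor, since no floor was used, the mean of a gene's probes and all gene list tests, since probes had no gene names. No paired analysis was possible because replicate numbers only name the samples. Signal over background was not given, so how far dim probes limit the counts is unknown.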

Other observations

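Which probes had a listed value was compared between the groups. At day 7, 12 probes were listed on at least 5 MI arrays and at most 1 sham array, and 1 probe the other way round; 9 of 100 splits of those arrays gave as many or more, the highest 23, so chance cannot be excluded. At day 1 the counts were 4 and 0, with 30 of 100 splits as large and 93 in the highest, so chance cannot be excluded there either, and without the sparse arrays, with the limits scaled to the arrays left, 13 and 4 (17 in all, and 18 in the highest of the other splits, which number too few to exclude chance). Between the days, 36 probes in sham and 41 in MI were mostly listed at day 7 and hardly at day 1, against 0 in each the other way; without the sparse arrays these became 9 against 3 and 12 against 4. With all arrays, 4 of 100 splits in sham (highest other 83) and 1 of 100 in MI (highest other 36) were as large; without the sparse arrays 15 of 84 (highest other 46) and 12 of 84 (highest other 34) were, so chance cannot be excluded for the counts that remain.

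The hypothesis that some probes are listed more often after infarction on both days was tested over all 12 MI and 12 sham arrays with Fisher's exact test. Of 922 probes, 17 had an unadjusted p under 0.05, 16 listed more often in MI and 1 more often in sham, and 0 passed Benjamini-Hochberg adjustment. Probe R575, chosen after its values were seen, was listed on 9 of 12 MI arrays (3 at day 1, 6 at day 7) and on 0 of 12 sham arrays (two-sided Fisher's exact p = 0.000337, adjusted p = 0.310), at 61.6 ± 11.2 (SD, n = 6) in day 7 MI and 62.8 ± 20.8 (SD, n = 3) in day 1 MI. When operations were redrawn within days, with the test fixed before its result was seen, 13 of 100 splits gave at least 17 such probes and the highest other gave 50, so chance cannot be excluded. These redraws did not keep 3 sparse arrays per operation as in the real grouping, which may raise the counts of other splits. A redraw that keeps them was not run.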
